A study of Mus musculus with 2 samples.

How the data were processed

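Total RNA longer than 200 bases from mouse forebrain at embryonic day 13.5 was extracted with a mirVana kit, per the labels' protocols, and the labels link the manual of a low-input cDNA kit. The labels give an input of 10 ng, added spike-in RNA and 2 biological replicates, 1 library each. The deposited tables were made by the authors from transcriptome alignments to mm10 with GENCODE annotation M4, per the file headers and the metadata deposited with them. The aligner, the quantification version, the read length and whether counting used strand are not given in the sources used here.

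Per the file headers, each library has a gene table and a transcript table with columns in the style of RSEM. The deposited expected counts are the authors' estimated counts of reads per gene or transcript, in which a read shared by several features is divided between them. The deposited TPM values are the authors' length-normalised relative abundances over all rows of a table, spike-ins included, with a second TPM column holding the posterior mean. The deposited FPKM values are the authors' fragment counts scaled by effective length and library size. The deposited percent column gives a transcript's share of its gene, and the shares printed here were recomputed from TPM. The deposited interval bounds of TPM were used only to see whether libraries overlapped, since their level is not stated. The deposited effective length equals the length minus 99 bases, and shorter rows are listed at 0 by construction, so TPM of genes slightly above 99 bases is inflated.

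Each gene table has 69691 rows, of which 43346 are mouse genes, and 42462 of these matched GENCODE M21 on GRCm38 by identifier, which gave symbols, classes and coordinates on the same assembly. The remaining 884 mouse genes entered no gene list and no comparison of single genes. They were part of the edgeR and DESeq2 scaling, the dispersion, the chi-square comparison and the totals behind class shares. The 26248 rows named by a number entered only those totals. Where several identifiers held one symbol, the one with the highest mean count was kept (20 identifiers dropped). Depth was 35378462 estimated counts for replicate 1 and 36793284 for replicate 2. A count of 0 allows 3 counts, which was converted to TPM for each gene and library.

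Samples were grouped by the labels into 1 group. Levels are means of 2 libraries with the SD. List levels are medians over members of the mean TPM of both libraries, with the SD of the medians taken in each library, and are ranked among 10000 random lists of protein-coding genes of the same size. The 11 list contrasts are differences of median log2(TPM + 1) within each library. List differences between libraries are medians over members with a mean expected count of at least 10, ranked among 10000 random lists matched on mean TPM in 20 bins. They were not computed for Hox genes, which left fewer than 3 such members. An exact two-sided sign test on 2 values cannot give a p below 0.5, so none was run. Counts were rounded to whole numbers for edgeR 4.0.16 (TMM, common dispersion) and DESeq2 1.42.0 (size factors), in R 4.3.3. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and BLAST 2.17.0. The bootstrap of the correlation drew genes 1000 times.

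The 38 gene lists, 16 isoform genes, contrasts, thresholds, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names, for levels, the 4 members of each list with the highest mean TPM and the 1 with the lowest, plus the 15 highest protein-coding genes of the nuclear genome. For differences it names the 10 protein-coding genes highest in each library by log2 ratio of TPM + 1, among those with a mean expected count of at least 100. For isoforms it names every gene of that list. Some genes that the rule names are not reported here, fewer were printed in places, and Gm22133, Gm28437, Gm10925, Hba-x, Hbb-bs and the named liver and muscle genes were singled out after their values were seen. Some genes are in more than 1 list (such as Pax6, Neurog2, Lhx2, Gad2 and Sox9), so lists are not independent.

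The dispersion estimate was tested on simulated counts for these genes: simulated values of 5%, 10% and 20% came out as 4.88%, 9.93% and 19.8%, over 17024, 17031 and 16886 genes. The list ranking was tested on the comparison of the replicates over 17297 genes with 10 genes per list and 20 lists per fold: it found 80.0% of lists changed 1.2-fold and 100% of those changed 1.5-fold or 2-fold, and it called 5.00% of unchanged lists in the first setting and 0 in the others. Alternatives tried were other thresholds, pseudocounts, count minimums, scalings, estimates and summaries, and leaving out each library. A length and GC correction was added after the data were seen. Near-identical copies of pseudogenes were sought with blastn at 95% identity over 80% of the length. The longest transcript of each gene was searched and the best single alignment was scored. The 8 further lists (second lists of choroid plexus, hypothalamus, thalamus, cortical hem, cortical neurons, striatal neurons, muscle and heart, liver and yolk sac) were written after the first values had been seen and before their own medians were. The choroid plexus, cortical neuron, muscle and liver lists share no gene with the first lists or with the 20 genes furthest apart between the libraries, and the others do (such as Gsx1, Nkx2-2 and Fezf1 for hypothalamus, Sox14 for thalamus, Wnt3a and Bmp7 for cortical hem, Six3 and Ebf1 for striatal neurons). Tests of explanations for the spike-ins were also written, and were dropped in favour of the liver and muscle lists before they were run. The count of spike-ins higher in replicate 2, which 1 of them would have used, was computed later and is given without an explanation.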

Results

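Total RNA from the forebrain of mouse embryos at embryonic day 13.5 was sequenced in 2 libraries, which form 1 group. The forebrain at this age holds the dividing cells of the cortical and basal ventricular zones and the first neurons that leave them. The tissue came from pooled male and female embryos of the B6NCrl strain, and each library was made from 10 ng of RNA. The labels call the libraries biological replicates from separate tissue samples that carry the same donor code. The libraries held 35378462 (replicate 1) and 36793284 (replicate 2) estimated counts. With 1 group of 2 libraries no test between conditions exists, so no p-values are given and errors are SDs of 2 libraries (n = 2) unless stated otherwise. Floors given for a count of 0 cover counting error only.

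Among protein-coding genes of the nuclear genome Tuba1a, an alpha-tubulin of young neurons (chromosome 15, 98949837 to 98953703, mm10), led with 9976 ± 507 TPM (SD, n = 2). It was followed by Actb at 6103 ± 139 TPM, the actin-binding peptide gene Tmsb4x at 6049.7 ± 1099 TPM, the imprinted gene Nnat at 5782 ± 625 TPM, the ferritin light chain gene Ftl1 at 5628 ± 129 TPM and the microtubule regulator Stmn1 at 5618 ± 126 TPM. Among the 15 highest genes were also Hba-a2, Hist1h2ap, Ppia, Ubb, Eef1a1, H3f3a, Tmsb10, Hbb-y and Actg1, between 4899 ± 55.6 TPM for Hba-a2 and 2828 ± 239 TPM for Actg1. Hba-a2 and Hist1h2ap share reads with near-identical copies, so their levels are uncertain. Of 21460 protein-coding genes, 12651 (59.0%) reached a TPM of at least 1 in both libraries, 1582 reached 100, and 4323 had no count in either.

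Both libraries gave nearly the same profile. Over the 21460 protein-coding genes the log2(TPM + 1) values correlated across genes with Pearson's r = 0.997 (bootstrap interval over genes, 95%: 0.997 to 0.998) and Spearman's rho = 0.991. Genes are not independent replicates. The median absolute log2 difference was 0.086. Of 12701 genes with a mean expected count of at least 100, 71 (0.559%) differed by at least 2-fold in TPM without a pseudocount. Of these, 61 were higher in replicate 1 and 10 higher in replicate 2. With counts scaled by TMM the split was 43 and 15. The biological coefficient of variation, estimated with edgeR over 16867 genes, was 8.62%. A chi-square comparison of the counts of both libraries gave 10.5 per degree of freedom over 18385 degrees of freedom, more than sampling noise alone, as separate preparations of a single sample would also give. The libraries were counted as 2 samples because the labels call them so.

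The first comparison asks which brain region the gene profile belongs to. Transcription factors of the forebrain, of its dorsal part (pallium) and of its ventral part (subpallium) were abundant, whereas genes of the midbrain, hindbrain and more caudal neural tube were near the detection limit. The 14 forebrain identity genes had a median of 26.3 ± 4.95 TPM (SD of the library medians, n = 2), at percentile 98 of 10000 random lists of the same size. They were led by Lhx2 (133 ± 10.3 TPM), Meis2 (107 ± 0.403 TPM) and Nr2f1 (81.6 ± 10.1 TPM). Hesx1, an early marker of the anterior neural plate, had no count in either library, which allows up to 0.13 TPM in replicate 1 and 0.119 TPM in replicate 2. The other 13 members reached 1 TPM in both libraries. Of 34 lists that could be ranked this way, 11 lay above the central 95% of random lists and 2 below it.

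The pallium list had a median of 37.9 ± 3.77 TPM over 14 genes (percentile 99.6), with all 14 at 1 TPM or more in both libraries. Its highest members were the neuronal factor Neurod6 (201 ± 79.1 TPM), the proneural factor Neurog2 (114 ± 16.2 TPM), Pax6 (74.2 ± 2.02 TPM) and Emx1 (66.9 ± 2.28 TPM), and its lowest was Bhlhe22 (4.7 ± 0.948 TPM). The subpallium list had a median of 27.4 ± 0.474 TPM over 15 genes (percentile 98.7), all 15 at 1 TPM or more. It was led by Dlx1 (234 ± 1.65 TPM), Dlx5 (72.6 ± 3.26 TPM), the GABA-synthesis gene Gad2 (71.4 ± 1.27 TPM) and Isl1 (71.3 ± 6.97 TPM), with Gsx1 lowest at 3.64 ± 0.481 TPM. Antisense transcripts overlap some Dlx genes, and whether counting used strand is not given in the sources used here. The log2 difference of the medians, pallium minus subpallium, was 0.43 ± 0.12 (SD, n = 2), larger than the spread between the libraries, and 0.25 with means over members. That spread covers the libraries only, and not the spread among list members.

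Genes of the diencephalon and hypothalamus were lower and mixed, with a median of 2.94 ± 1.17 TPM over 14 genes (percentile 40.4), or 5.27 TPM by the mean of log2 values. The thalamic factor Tcf7l2 reached 141 ± 46.6 TPM, Lhx9 27.8 ± 0.912 TPM, Gbx2 20.1 ± 6.0 TPM and the hypothalamic hormone precursor Pomc 14.7 ± 6.24 TPM, whereas Nkx2-4 was at 0.23 ± 0.212 TPM. Forebrain identity genes lay 2.74 ± 0.14 log2 units above this list (SD, n = 2), and 1.72 over members at 1 TPM or more. Of the 14 midbrain and hindbrain genes, 12 stayed under 1 TPM in both libraries, and the median was 0.0525 TPM over the means of both libraries (0.075 and 0.055 in replicates 1 and 2 alone; percentile 1.54), or 0.178 with posterior mean TPM and 0.401 by the mean of log2 values. The roof plate factor Lmx1a was among the exceptions, at 4.9 ± 4.01 TPM. All 16 Hox genes, which mark the hindbrain and spinal cord, were under 1 TPM, with a median of 0.01 TPM (0 in each library alone, 0.055 with posterior mean TPM), 6 counts in replicate 1 and 9 in replicate 2. Hoxb5 was highest at 0.065 ± 0.0212 TPM. Forebrain identity minus midbrain and hindbrain was 4.71 ± 0.24 and minus Hox genes 4.80 ± 0.26 on the log2(TPM + 1) scale, which understates differences against genes near 0. With a pseudocount of 0.1 they were 7.36 and 8.07, and over members at 1 TPM or more the first was 2.18.

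**Figure D1:**
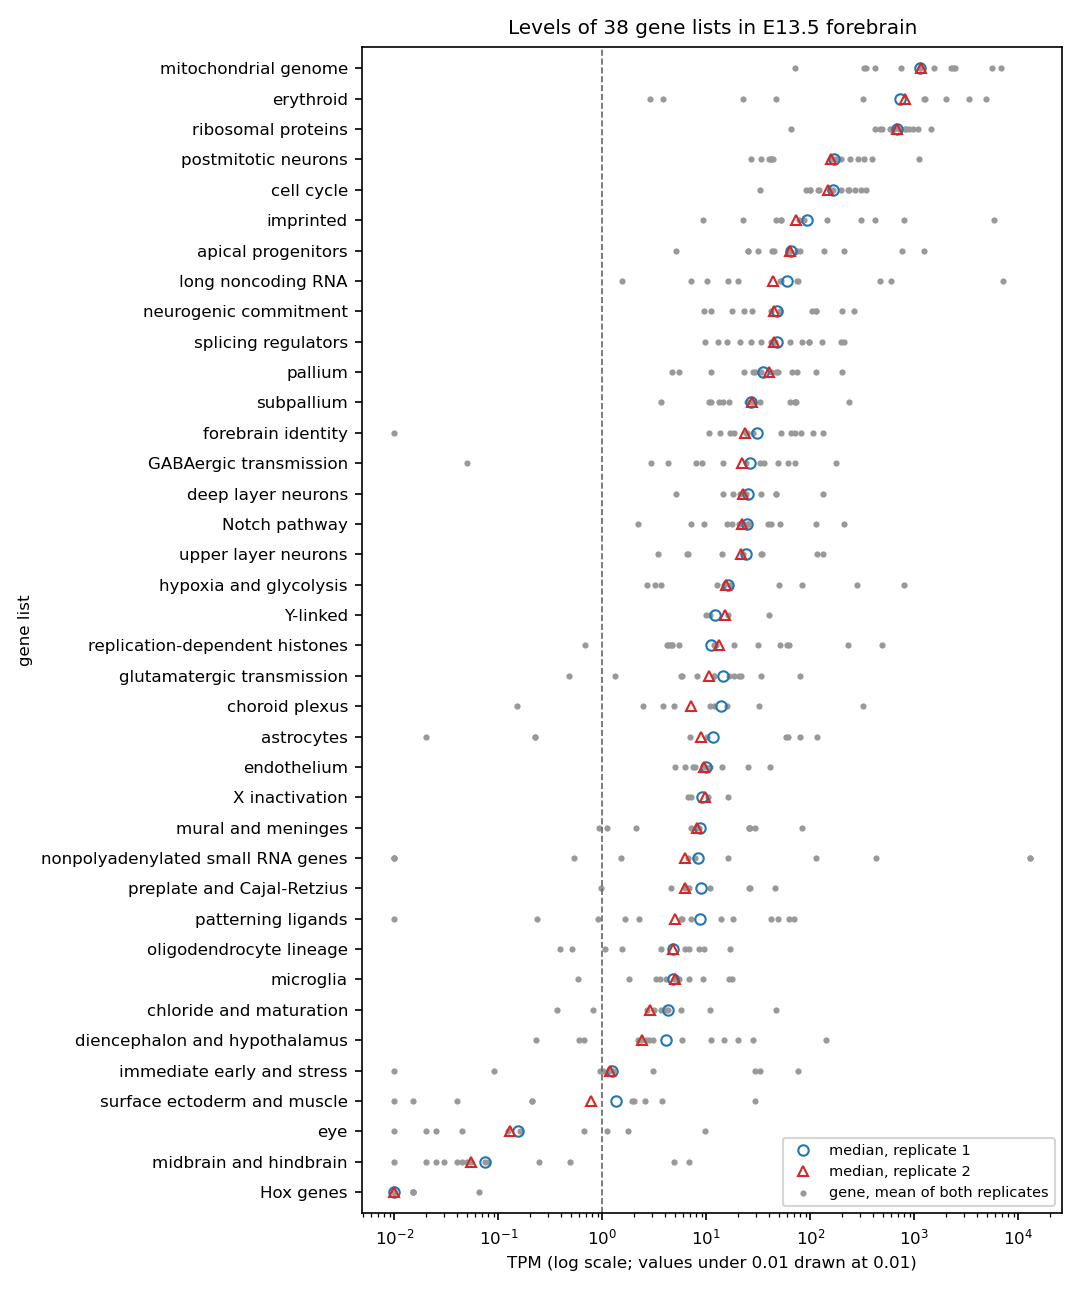
Each row shows one of 38 gene lists, with the TPM of every member on a log axis (grey points, mean of 2 libraries) and the median in replicate 1 (circle) and in replicate 2 (triangle), and the dashed line marks 1 TPM. Hox genes (median 0.01 TPM) and midbrain and hindbrain genes (median 0.0525 TPM) lie at the bottom, and the pallium list (median 37.9 TPM) lies far to the right of the line.

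The next comparison sets dividing progenitors against neurons. Both were strongly represented, with markers of postmitotic neurons above those of apical progenitors, the dividing cells that line the ventricle. Apical progenitor genes had a median of 64.2 ± 1.38 TPM (percentile 99.99), led by the fatty acid binding protein gene Fabp7 (1227 ± 53 TPM), the filament gene Vim (759 ± 18.5 TPM), the Notch target Hes5 (211 ± 16.6 TPM) and Id4 (136 ± 49.6 TPM), with Tnc at 5.16 ± 1.28 TPM. Genes of neurogenic commitment had a median of 46.5 ± 2.11 TPM (percentile 99.8) and were led by Hes6 (264 ± 9.09 TPM) and Gadd45g (202 ± 6.46 TPM), with Insm1 at 9.44 ± 1.53 TPM. Neuronal genes had a median of 164 ± 8.68 TPM, above every random list, with the neuronal tubulin gene Tubb3 at 1116 ± 63.4 TPM, Stmn2 at 390.4 ± 3.56 TPM, Gap43 at 331 ± 4.7 TPM, Map2 at 287 ± 23.2 TPM and Rbfox3 at 27.1 ± 1.65 TPM. Progenitor minus neuronal genes was -1.34 ± 0.045 log2 units (SD, n = 2), and -0.74 with means over members. These are levels in a mixed tissue and give no cell numbers.

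Cell cycle genes were also high, with a median of 153 ± 11.3 TPM over 15 genes (above every random list). The cyclin gene Ccnd2 (340.3 ± 21.8 TPM), the kinase gene Cdk1 (306 ± 13.1 TPM), the replication clamp gene Pcna (269 ± 7.1 TPM) and Ccnb1 (236 ± 16.5 TPM) led, and Mki67 was lowest at 32.8 ± 1.54 TPM. The Notch pathway had a median of 23.2 ± 1.78 TPM (percentile 97.4), from Hes5 (211 ± 16.6 TPM) to Jag2 (2.23 ± 0.318 TPM). Patterning ligands had a median of 6.48 ± 2.6 TPM (percentile 63.8), with Wnt7b at 68.9 ± 6.06 TPM and the Wnt inhibitor gene Sfrp1 at 62.1 ± 1.07 TPM, whereas Wnt1, a midbrain signal, was at 0.01 ± 0.0141 TPM. Regulators of splicing had a median of 45.9 ± 2.16 TPM (percentile 99.9), led by the neuronal regulator Ptbp2 (213 ± 8.51 TPM), with Elavl4 at 196 ± 14.5 TPM and Mbnl2 at 9.79 ± 0.297 TPM.

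Among cortical neurons, genes of deep and of upper layers had close medians. Deep layer genes had a median of 24 ± 1.8 TPM (percentile 94), with Sox5 at 132 ± 21.2 TPM, Fezf2 at 47 ± 4.09 TPM, Bcl11b at 47 ± 3.6 TPM and Zfpm2 at 5.08 ± 0.375 TPM. Upper layer genes had a median of 22.8 ± 1.9 TPM (percentile 93.1), with Lhx2 and Cux1 highest (Cux1 116 ± 4.5 TPM) and Unc5d lowest at 3.42 ± 0.0566 TPM. Lhx2, and other genes of the upper layer list, are also used in dividing progenitors. The deep minus upper difference was 0.075 ± 0.011 log2 units (SD, n = 2), small but larger than the spread between the libraries, and 0.29 with means over members. The spread between the libraries does not cover the spread among list members, so the lists are not shown to differ. Preplate and Cajal-Retzius genes, which mark the earliest cortical neurons, had a median of 6.81 ± 1.82 TPM (percentile 63.6), led by Calb2 (45.6 ± 7.01 TPM) and the migration cue Reln (26.6 ± 2.03 TPM), with Ebf3 at 0.975 ± 0.361 TPM.

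Genes of GABAergic transmission exceeded those of glutamatergic transmission, with medians of 24.3 ± 2.96 TPM (percentile 96.8) and 11.9 ± 2.71 TPM (percentile 81.8). The glutamatergic minus GABAergic difference was -0.92 ± 0.12 log2 units (SD, n = 2). The interneuron peptide gene Sst reached 177 ± 46.7 TPM and Npy 60.9 ± 8.14 TPM, while Pvalb, a marker of mature interneurons, was at 0.05 ± 0.0707 TPM. On the glutamatergic side the receptor gene Gria2 had 79.8 ± 1.03 TPM, the vesicular transporter gene Slc17a6 33.9 ± 2.93 TPM and Grin2d 0.48 ± 0.0707 TPM. The list of chloride transport and maturation was low, with a median of 3.88 ± 1.03 TPM (percentile 45.5), with Nefh lowest at 0.37 ± 0.0849 TPM.

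Other cell types of the dissected tissue were compared with neurons. Markers of astrocytes and oligodendrocytes lay far below neuronal genes, and globin transcripts of red blood cells lay above them. Astrocyte genes had a median of 10.2 ± 1.88 TPM (percentile 74). The list was split between genes that progenitors also use, such as Aldoc (115 ± 2.23 TPM) and Sox9 (79.7 ± 0.834 TPM), and Gfap, the filament of mature astrocytes, at 0.02 ± 0.0283 TPM. Oligodendrocyte genes had a median of 4.98 TPM over the means of both libraries (4.76 and 4.75 in replicates 1 and 2 alone; percentile 52.1), led by Cnp (17 ± 0.12 TPM) and the myelin gene Mbp (9.41 ± 1.22 TPM), with Sox10 at 0.395 ± 0.0212 TPM. Neuronal genes lay 3.89 ± 0.17 log2 units above astrocyte genes and 4.87 ± 0.050 above oligodendrocyte genes (SD, n = 2). Over astrocyte genes at 1 TPM or more the first difference was 1.45. Microglial genes had a median of 4.86 ± 0.141 TPM (percentile 55.4), with the complement gene C1qb at 16.4 ± 0.502 TPM and Ptprc at 0.58 ± 0.325 TPM.

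Endothelial genes had a median of 9.78 ± 0.325 TPM (percentile 72.8), with the tight junction gene Cldn5 at 40.7 ± 4.39 TPM and Tek at 4.96 ± 0.29 TPM, and lay 0.88 ± 0.078 log2 units above microglial genes (SD, n = 2). Mural and meningeal genes had a median of 8.5 ± 0.396 TPM (percentile 70.8), led by the collagen gene Col3a1 (82.8 ± 2.6 TPM), with Anpep at 0.92 ± 0.368 TPM. Erythroid genes had a median of 774 ± 56.5 TPM (above every random list), or 219 TPM by the mean of log2 values, and neurons minus erythroid genes was -1.91 ± 0.00033 log2 units (SD, n = 2), and -0.81 with means over members. Hba-a2 reached 4899 ± 55.6 TPM, the embryonic globin gene Hbb-y 3317 ± 541 TPM, Hba-a1 1992 ± 54.9 TPM and Hbb-bt 1263 ± 152 TPM. Hba-a1 and Hba-a2 are near-identical, as are Hbb-bt and Hbb-bs, so the split within each pair is uncertain. Choroid plexus genes had a median of 10.9 ± 4.74 TPM (percentile 75.7; 13.8 in replicate 1 and 7.1 in replicate 2), led by the thyroxine carrier gene Ttr (319 ± 143 TPM), with Kl at 0.15 ± 0.0283 TPM. Eye genes (median 0.143 ± 0.0177 TPM, percentile 5.63) and surface ectoderm and muscle genes (median 1.07 ± 0.407 TPM, percentile 21) were low, apart from the pigment gene Dct (9.79 ± 0.29 TPM) and the cartilage collagen gene Col2a1 (29.4 ± 5.18 TPM). By the mean of log2 values eye genes were at 0.641 TPM.

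The libraries were then compared with each other. Choroid plexus genes were lower in replicate 2, all 9 measured members included, with a median log2 ratio (replicate 2 over replicate 1) of -0.73, and Ttr had 420.0 TPM in replicate 1 and 217 TPM in replicate 2. Preplate and Cajal-Retzius genes (-0.37, 9 of 9 lower), erythroid genes (-0.25, 8 of 10 lower), GABAergic (-0.27, 9 of 12 lower) and glutamatergic transmission (-0.26, 10 of 13 lower) were also lower in replicate 2. So were the maturation list (-0.29, 10 of 10 lower), surface ectoderm and muscle genes (-0.40, 6 of 6 lower) and imprinted genes (-0.22, 11 of 12 lower). Pallium genes were higher in replicate 2 (0.12, 10 of 14 higher), as were Y-linked genes (0.38, 4 of 4 higher), histone genes (0.15, 11 of 15 higher), small RNA genes without a poly(A) tail (0.14, 5 of 6 higher), neurogenic commitment (0.054, 7 of 12 higher), subpallium (0.043, 10 of 15 higher) and mural and meningeal genes (0.041, 8 of 11 higher). The small RNA median is set by Rn7s1 and Rn7s2 (0.14 each), near-identical copies that share reads. It therefore rests in effect on a single RNA, while its ranking below treats the members as separate genes.

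These 15 of 37 lists lay outside the central 95% of 10000 expression-matched random lists, 8 of them below and 7 above. For lists of genes drawn independently, 1.85 would lie outside by chance. Members of a marker list can move together and some lists share genes, so 15 against 1.85 does not measure an excess over chance. The median log2 ratio of all genes was -0.097 with TPM and 0.00064 with TMM-scaled counts, so list values are to be read against that shift. With TMM-scaled counts the called lists that moved by over 1.5 times were pallium (0.24), subpallium (0.20), neurogenic commitment (0.18), mural and meningeal (0.17), histone (0.26), small RNA (0.26), erythroid (-0.096), GABAergic (-0.17) and imprinted genes (-0.096), and 5 of 10 erythroid genes were then lower. The median TPM went the other way in replicates 1 and 2 for the erythroid (734 and 814 TPM), neurogenic commitment (48 and 45 TPM), mural and meningeal (8.78 and 8.22 TPM) and small RNA lists (8.24 and 6.28 TPM), since the median of ratios is not the ratio of medians. Removing the length and GC trend, chosen after seeing the data, likewise moved preplate and Cajal-Retzius (-0.24), glutamatergic (-0.12) and maturation genes (-0.16), and a pseudocount of 0.1 surface ectoderm and muscle genes (-0.74). Of the 15 lists, 12 lay outside on the same side in all 6 settings tried, and the exceptions were the maturation list, surface ectoderm and muscle, and the small RNA genes. Diencephalon and hypothalamus genes (-0.23) lay at percentile 2.51, just inside. The percentiles describe these 2 libraries and are no test of a condition.

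**Figure D2:**
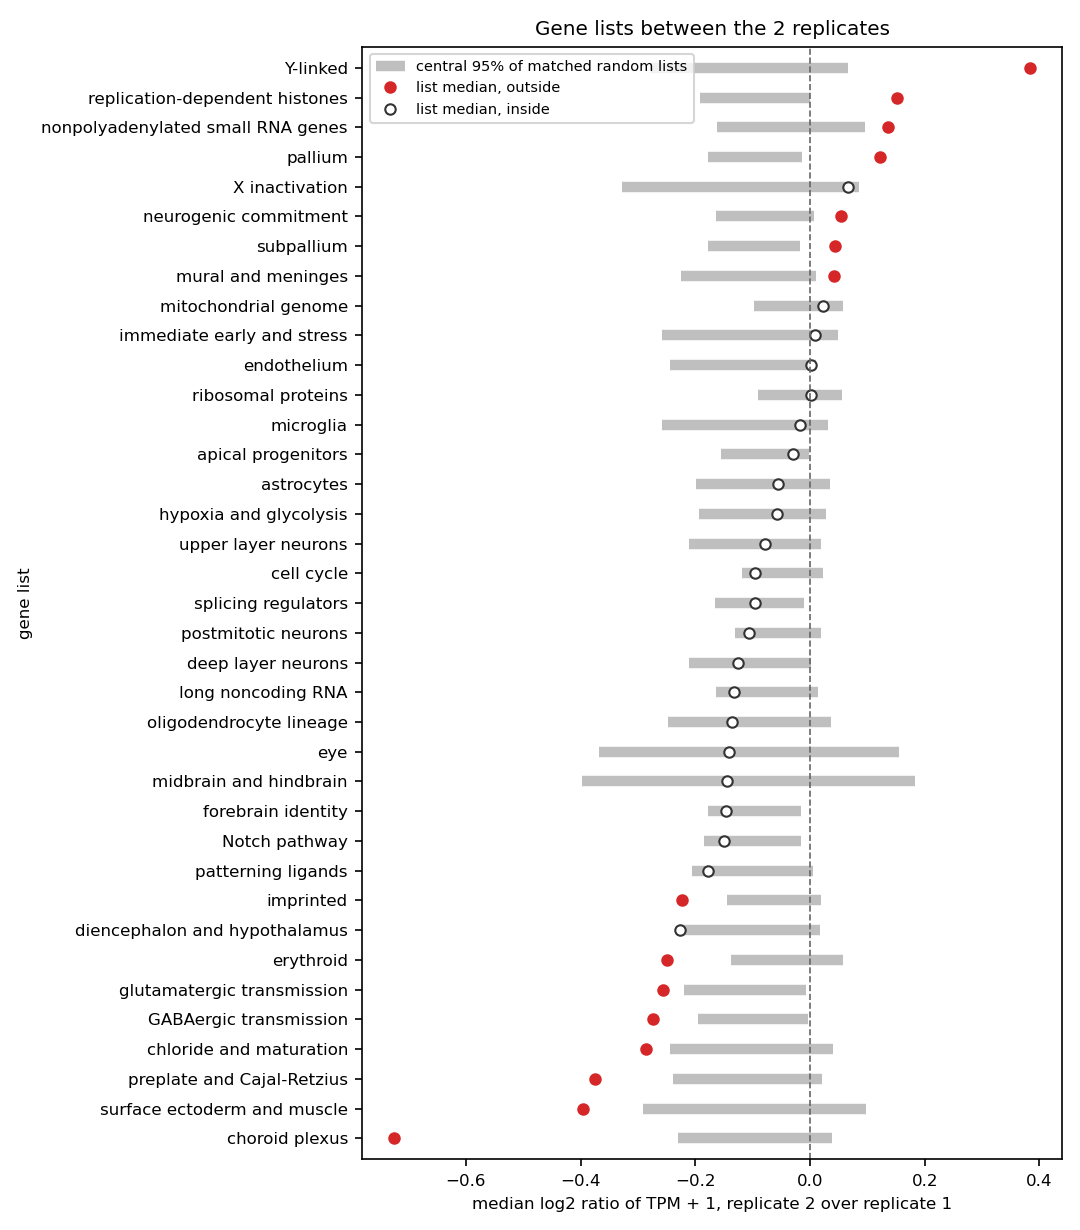
The x axis gives the median log2 ratio of TPM + 1, replicate 2 over replicate 1, of 37 gene lists (points), with the central 95% of matched random lists as grey bars, and filled points lie outside their bar. The choroid plexus list lies furthest left at -0.73 and the Y-linked list furthest right at 0.38.

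The largest differences among protein-coding genes with a mean expected count of at least 100 were in Actc1, the actin of heart and fetal muscle (chromosome 2, 114047282 to 114053548, mm10), with 32.4 TPM in replicate 1 and 2.22 TPM in replicate 2, and in Afp, the alpha-fetoprotein of fetal liver and yolk sac, with 7.33 TPM in replicate 1 and 0.15 TPM in replicate 2. The peptide gene Cck had 32.2 and 7.96 TPM in replicates 1 and 2, the homeobox gene Alx1 had 4.94 and 0.67 TPM, and Lmx1a had 7.73 and 2.06 TPM. Fezf1 (33.8 and 11.6 TPM), the peptide gene Cartpt (15.7 and 5.43 TPM), Zfp781 (12.5 and 3.41 TPM) and the embryonic globin gene Hbb-bh1 (68 and 26.3 TPM) were also higher in replicate 1.

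In the other direction Neurod6 had 145 TPM in replicate 1 and 257 TPM in replicate 2, Id4 had 101 TPM in replicate 1 and 171 TPM in replicate 2, and Nkx2-1, the factor of the medial ganglionic eminence and hypothalamus, had 10.5 TPM in replicate 1 and 18.6 TPM in replicate 2. Syt13 (15.6 and 30.4 TPM in replicates 1 and 2), Pomc (10.3 and 19.1 TPM), Cabp1 (4.69 and 10.3 TPM), Gm11627 (7.42 and 14.1 TPM), Sox14 (3.53 and 6.65 TPM), Pou4f1 (2.24 and 4.58 TPM) and BC037034 (3.03 and 6.1 TPM) were likewise higher in replicate 2. All 20 genes furthest apart kept their direction with TMM-scaled counts, and the deposited TPM intervals of the libraries did not overlap for any of them but BC037034 and Zfp781. The genes were chosen for their large differences in these same libraries, so neither is further support.

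**Figure D3:**
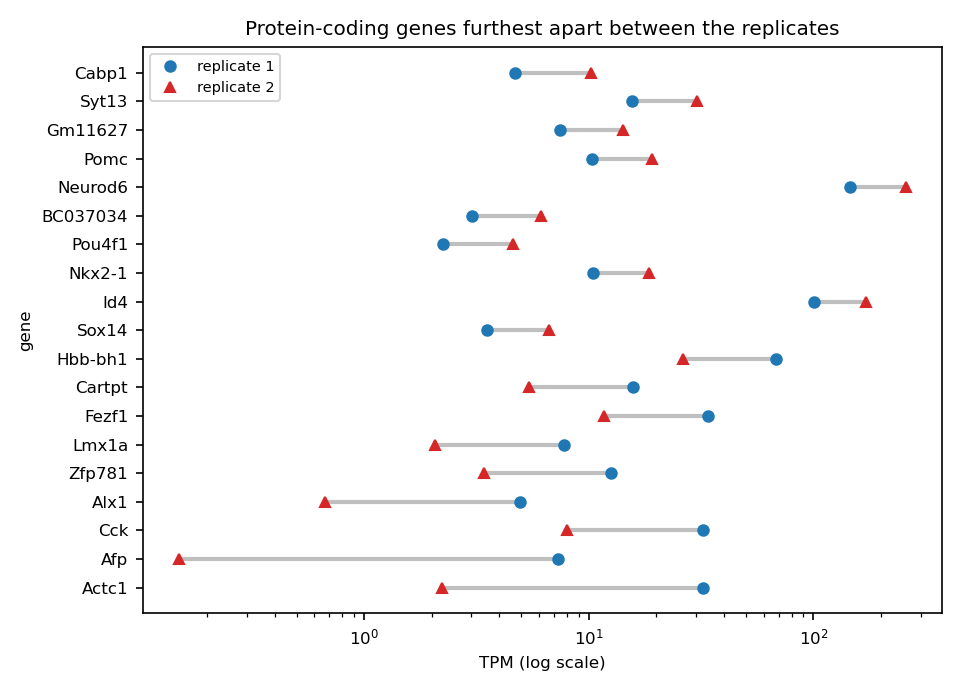
TPM on a log axis of protein-coding genes furthest apart between replicates 1 and 2 by log2 ratio, with a point for each library. Actc1 spans 2.22 to 32.4 TPM and Neurod6 spans 145 to 257 TPM.

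RNA classes were compared by their share of all counts. Protein-coding genes of the nucleus took 91.9% ± 0.808 (SD, n = 2), long noncoding genes 2.14% ± 0.0668, the mitochondrial genome 1.63% ± 0.0903, pseudogenes 1.49% ± 0.0817 and small or structural RNA 0.354% ± 0.0343. Long noncoding genes held 740543 counts in replicate 1 and 804932 in replicate 2. Much of this lay in neighbouring genes of chromosome 17, Gm42418 (144625 and 178535 counts) and Gm26917 (118489 and 127512 counts). Spike-in RNA took 2.27% ± 0.532, at 1.9% in replicate 1 and 2.65% in replicate 2. By summed TPM, shares were 3.12% mitochondrial, 4.96% pseudogene, 3.32% small or structural RNA and 5.27% spike-in. Mitochondrial genes had a median of 1139.6 ± 12.7 TPM, or 1751 with posterior mean TPM, with mt-Atp6 at 6736 ± 668 TPM and mt-Nd4l at 71.5 ± 6.12 TPM, and ribosomal protein genes had a median of 679 ± 6.76 TPM, from Rpl32 (1453 ± 160.4 TPM) to Rpl5 (64.7 ± 2.13 TPM). The replication-dependent histone list held 32 symbols, the older and newer names of 16 genes, and all 16 genes were matched. Their median was 12.1 ± 1.56 TPM (percentile 85.4), from Hist1h4d (484 ± 16.6 TPM) to Hist1h4a (0.675 ± 0.219 TPM). Hist1h2ap, named above among the highest protein-coding genes, is not in this list. Histone copies share reads, so single members are uncertain.

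The small RNA genes without a poly(A) tail had a median of 7.26 ± 1.39 TPM, or 11.4 with posterior mean TPM and 22.8 by the mean of log2 values. The signal recognition particle RNAs Rn7s1 (12987 ± 869.9 TPM) and Rn7s2 (12986 ± 871 TPM), which are near-identical copies, led, followed by Rn7sk (429.7 ± 59.6 TPM) and Rpph1 (112 ± 14.3 TPM), and Rnu11, Rnu12 and Rny3 had no count. Among other RNAs Malat1, a nuclear long noncoding RNA, reached 7176 ± 847 TPM. Its deposited length is 523 bases, although the gene spans 5795690 to 5802672 on chromosome 19. A longer length would lower its TPM, so this level is uncertain. Gm22133, annotated as a microRNA gene of 109 bases, was listed at 4557 ± 783 TPM. It lies within Ftl1 on the same strand and has an effective length of 10 bases, so its reads cannot be told from those of Ftl1. Rows under 200 bases that were longer than 99 bases held under 0.1% of the counts.

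Transcript shares were computed for 16 genes with known alternative isoforms. In 9 of them a single transcript held at least 50% of the gene's TPM, and 15 of 16 genes had the same main transcript in both libraries; both counts include Ptbp2, which had 1 annotated transcript and could not differ. Pkm, which encodes pyruvate kinase, was 79.3% ± 0.801 Pkm-201 (SD, n = 2), and Cdc42 was 68.4% ± 0.322 Cdc42-202. The adhesion gene Ncam1 was 85.5% ± 0.29 Ncam1-204, Tpm3 83.9% ± 1.54 Tpm3-201, Camk2g 77.8% ± 1.34 Camk2g-203, Snap25 76.9% ± 1.18 Snap25-201, Rbfox2 72.3% ± 0.828 Rbfox2-203 and Nrcam 53.4% ± 3.68 Nrcam-202. The main transcripts of Mapt (Mapt-205, 47.3% ± 0.00939), Clta (Clta-204, 46.7% ± 0.697), Numb (Numb-204, 44.6% ± 1.93), Map2 (Map2-201, 36% ± 1.79), Gria2 (Gria2-206, 35.3% ± 0.501) and Meis2 (Meis2-206, 24.3% ± 0.215) held less. Gria2-206 is annotated as a retained intron and not as protein-coding, and the protein-coding Gria2-202 came second with 31.9% ± 0.218. For Dnm2 the main transcript differed between the libraries, and Dnm2-201 held 32.9% in replicate 1 and 43.5% in replicate 2. By expected counts instead of TPM, Mapt-205 held 26.9%, Numb-204 64.7% and Map2-201 50.4%, and 11 genes reached 50%. The shares rest on the authors' division of reads between overlapping transcripts.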

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

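Signals lay in rows that entered no gene list and no comparison of single genes, above the 3 counts that a count of 0 allows. The 26248 rows named by a number held 21.6 estimated counts in replicate 1 and 17 in replicate 2; only 63 of these rows exceed 99 bases, so the others are listed at 0 by construction. The 884 mouse genes without a match in the M21 annotation held 76208 and 80779 estimated counts, which is 0.217% ± 0.00293 of the total (SD, n = 2). These 884 genes did enter the count scaling, the dispersion and the chi-square comparison. No explanation was tested for either set of rows.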

How the results depend on the processing

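The length and GC correction was chosen after seeing the data, and the cause of each shift below was not tested except where the setting itself sets it. No list that lay outside the random lists changed side. Leaving out either library kept the count of detected genes within 1.5 times. Contrasts and class shares are means of 2 libraries, so leaving 1 out cannot move them beyond the SD, and that setting could not test them. At 10 TPM, 8343 genes were detected. The correlation between libraries was 0.995 with a pseudocount of 0.1, 0.995 over genes at 1 TPM or more, 0.998 with posterior mean TPM and 0.998 with FPKM. Genes apart by 2-fold numbered 132 at a mean count of 50 or more and 3 at 1000 or more. By the mean of log2 values 17 lists lay above the central 95% of random lists, against 11. With a pseudocount of 0.1, contrasts were 8.07 (forebrain identity minus Hox), 7.36 (minus midbrain and hindbrain), 3.06 (minus diencephalon), 5.12 (neurons minus oligodendrocytes), 0.99 (endothelium minus microglia) and -1.92 (neurons minus erythroid). With members at 1 TPM or more, forebrain identity was 2.18 above midbrain and hindbrain and 1.72 above diencephalon, neurons were 1.45 above astrocytes and 4.33 above oligodendrocytes, and glutamatergic minus GABAergic was -0.76; no Hox gene was left, so that contrast has no value. With means over members, forebrain identity was 4.38 and 2.21 above midbrain and hindbrain and diencephalon, pallium minus subpallium 0.25, progenitors minus neurons -0.74, deep minus upper layers 0.29, neurons minus astrocytes 3.40, minus oligodendrocytes 4.74 and minus erythroid -0.81, glutamatergic minus GABAergic -0.64 and endothelium minus microglia 1.02. Between the libraries, TMM scaling also put outside the random lists the diencephalon (-0.18), upper layer (0.15), endothelium (0.17), patterning (-0.12), long noncoding (-0.075), X inactivation (0.18) and immediate early lists (0.15). A pseudocount of 0.1 added diencephalon (-0.48), patterning (-0.31) and long noncoding RNA (-0.19), and posterior mean TPM added diencephalon (-0.23). A mean count of at least 100 added immediate early genes (0.064) and lost maturation (-0.27) and surface ectoderm and muscle (-0.35), with fewer members left. Removing the length and GC trend added diencephalon (-0.14), cell cycle (-0.053) and endothelium (0.13) and lost the small RNA genes (0.12). By summed TPM, shares were 80.4% protein-coding, 5.27% spike-in, 4.96% pseudogene, 3.32% small or structural, 3.12% mitochondrial and 2.71% long noncoding.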

Other observations

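The tests of Ttr and of the choroid plexus list without it were chosen after the result was seen, and the other tests here were written before their values were seen, though the Actc1 and Afp pattern itself was picked from the data. Imprinted genes were among the highest lists, with a median of 82.8 ± 13.1 TPM over 12 genes (above every random list), or 126 TPM by the mean of log2 values. Ndn reached 789 ± 91.3 TPM, Mest 419 ± 70 TPM and Snrpn 304 ± 8.66 TPM, while Igf2r was at 9.23 ± 0.806 TPM. Of the 14 long noncoding RNAs written, 12 were measured, with a median of 51.6 ± 10.6 TPM. Meg3 (594 ± 119.5 TPM) and Pantr1 (468 ± 86.6 TPM) followed Malat1, whose TPM rests on a short deposited length, so its rank is uncertain. Neat1 was lowest at 1.55 ± 0.247 TPM. Y-linked genes had a median of 13.6 ± 1.99 TPM (percentile 68.5), with Eif2s3y at 40.3 ± 9.14 TPM and Uty at 9.99 ± 3.37 TPM. Genes of X inactivation had a median of 8.79 TPM over the means of both libraries (9.01 and 9.61 in replicates 1 and 2 alone), with Xist at 16 ± 0.926 TPM in the mixed-sex pools, and Xist and Tsix overlap on opposite strands.

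Immediate early and stress genes were low as a list (median 1.22 ± 0.0424 TPM, percentile 22.8, or 3.83 TPM by the mean of log2 values), but Jun stood at 76.7 ± 4.84 TPM, Dusp1 at 33 ± 0.0141 TPM and Ier2 at 29.3 ± 0.382 TPM, against 0.01 ± 0.0141 TPM for Fosb. Genes of hypoxia and glycolysis had a median of 15.9 ± 0.576 TPM (percentile 86.2), or 26.6 TPM by the mean of log2 values, led by Ldha (786 ± 65.7 TPM) and Pgk1 (278 ± 12.7 TPM), with Vegfa at 2.69 ± 0.629 TPM. Among the globins the embryonic genes Hba-x (382 and 261 TPM in replicates 1 and 2), Hbb-y (3699 and 2935 TPM) and Hbb-bh1 (68 and 26.3 TPM) were lower in replicate 2. The adult genes Hbb-bt (1155 and 1370.4 TPM) and Hbb-bs (1087 and 1367 TPM) were higher there, but the adult genes Hba-a2 (4938 and 4859.6 TPM) and Hba-a1 (2031 and 1954 TPM) were not. The direction of Hba-a2 depends on the scaling, since its log2 ratio was -0.023 with TPM and 0.10 with TMM-scaled counts. Hba-x and Hbb-bs were singled out after their values were seen. Of 43 spike-in RNAs with a mean count of at least 100, 42 were higher in replicate 2, with a median log2 ratio of 0.39.

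Second lists of markers gave these medians of the log2 ratio, replicate 2 over replicate 1. Cortical neurons were at 0.25, thalamus at 0.025, hypothalamus at -0.10, striatal neurons at -0.21 and cortical hem at -0.46. Against matched random lists, the cortical neuron and thalamus lists lay above the central 95%, the cortical hem list below it, and the hypothalamus and striatal lists inside. The cortical neuron and cortical hem lists stayed outside in the other settings run. At a mean count of at least 100 the hypothalamus (-0.45) and striatal lists (-0.27) lay below and the thalamus list (0.0026) inside. With TMM-scaled counts the striatal list (-0.17) lay below, while thalamus was at 0.12 and hypothalamus at -0.0093. With a pseudocount of 0.1 thalamus was at 0.041. Removing the length and GC trend, chosen after the data were seen, gave 0.15 for thalamus, 0.013 for hypothalamus and -0.099 for striatal neurons, with the hypothalamus and striatal lists inside.

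Choroid plexus genes were lower in replicate 2 (median log2 ratio -0.73). The values argue against TPM scaling, since the median stayed at -0.61 with TMM-scaled counts, and against gene length bias, since it stayed at -0.63 after the length trend was removed. They also argue against Ttr alone as the source, since 17 of 18 genes of a second list, which lacks Ttr, were lower in replicate 2. The 8 other members of the first list were lower too (median -0.64). That decides nothing further, since every member was lower and leaving out any 1 could not bring the median near 0. Liver RNA that brought other members as well stays open. More choroid plexus tissue in the replicate 1 sample also stays open: the second list was lower in replicate 2, with a median of -0.36, below every random list but short of the bound of -0.5 set in advance, which it passed with a pseudocount of 0.1 (-0.69) and over the 9 genes with a mean count of at least 100 (-0.58), but not with TMM-scaled counts (-0.44), posterior mean TPM (-0.37) or the length and GC trend removed (-0.28). The design has 1 group, so no biological explanation was tested.

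Actc1 and Afp were 14.6-fold and 48.9-fold higher in replicate 1. A candidate explanation is a trace of tissue from outside the forebrain, and it stays open. In a list of liver and yolk sac genes written without Afp, 12 of 14 genes were lower in replicate 2, with a median of -0.97 against a bound of -1 set in advance, which it passed with a pseudocount of 0.1 (-2.06) but not with TMM-scaled counts (-0.87), posterior mean TPM (-0.92) or the length and GC trend removed (-0.90): Alb had 4.44 and 0 TPM (192 counts and 0, which allows 3), Apoa1 4.52 and 0.97 TPM, Serpina1b 2.81 and 0.22 TPM and Trf 20.2 and 13.7 TPM, while Apoa4 went the other way at 0 and 0.89 TPM. In a list of muscle and heart genes written without Actc1, 10 of 12 were lower, with a median of -0.53 against the same bound, passed with a pseudocount of 0.1 (-1.25) but not in the other settings (-0.39, -0.44 and -0.50, in the same order); Tnnt2 had 7.76 and 0.3 TPM and Myh7 1.45 and 0.4 TPM. These genes were singled out after their values were seen, most are near the detection limit, and the pseudocount of 1 compresses their ratios. No biological explanation was tested.

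Of pseudogenes, 63 had a mean TPM of at least 100. Reads shared with a near-identical gene could account for many of them. Of the 63, 76.2% (48 of 63) matched a gene that is no pseudogene at 95% identity over 80% of their length. Of pseudogenes under 1 TPM, 33.3% (21 of 63) did so. The bound of 80% set in advance was not reached. Only the best single alignment to each gene's longest transcript was scored, so a match split into pieces could be missed in both sets. Gm12918 was identical to Rpl13 over 39.2% of its length, whereas Rps13-ps2 had only 84.3% identity to its best match. The shares may therefore be too low, and the bound does not decide the question. Of the 48, 6 matched mitochondrial genes, among them Gm28437 (7772 ± 96.2 TPM), which is identical to mt-Co3 over its length, and Gm10925 (751 and 1995 TPM in replicates 1 and 2), which is identical to mt-Atp6. Adding the counts of these 6 to the mitochondrial genome would raise its share from 1.63% to 2.22% ± 0.144 (SD, n = 2). The design gives no biological explanation, and none was tested.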
